A study of Mus musculus with 6 samples.

How the data were processed

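Whole tibiae of female mice 12 weeks old were studied, 3 samples of Col1a1+/- and 3 of wild-type genotype, per the labels. Marrow was flushed out, the bones were frozen and disrupted, RNA was extracted and libraries were prepared by poly-A selection, per the labels' protocols. Muscle or cartilage left on the bone, and marrow left inside it, would add its RNA to a library.

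The deposited files hold raw read counts per gene, 1 file per library, with no normalization, per the file headers. Trimmomatic 0.39, HISAT2 2.2.1 and SAMtools 1.20 were used before counting, per the submitters' processing notes, and the settings of trimming and alignment are not given in the sources used here. Reads were counted by featureCounts 2.0.3 over exons of the Ensembl release 107 annotation of the mouse genome build GRCm39, per the file headers. The recorded command names paired input without the option that counts pairs, so each mate of a pair counts as 1 read. Counts between 1 and 20 were even in 61.8% to 64.2% of cases per library, as pairs counted by their mates would give. The same command sets no strand, so reads of a gene and of an antisense partner cannot be told apart, and it leaves out reads that map to several places or overlap several genes. Families of near-identical genes, such as the Bglap, Serpina1 and globin genes, are therefore undercounted and uncertain. Of 86 genes followed by name, 5 shared over 10% of their exon length with another gene: Ccn2, Myh7, Pcna, Ppp1r1b and Uqcrc2, each with a gene on the opposite strand.

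Gene symbols and gene types came from a mouse annotation on an earlier genome build by matching gene identifiers, which named 52073 of 56748 identifiers (91.8%). Identifiers without a symbol took 0.245% to 0.304% of counts. Coordinates are those of the deposited files, on GRCm39, and no coordinate of the other build was used.

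Genes were kept by edgeR's filterByExpr with the genotype as the group, which left 18514 genes holding 99.87% to 99.9% of counts. Library sizes were scaled by the trimmed mean of M values (TMM), with factors between 0.892 and 1.1. Genotypes were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion estimates, genotype as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold, two-sided. A log2 fold change is Col1a1+/- over wild type, and its SE is the absolute log2 fold change divided by the square root of F. CPM values are counts-per-million after TMM, and scores of gene lists are means of log2 CPM with a prior count of 2. Single values were compared by an exact two-sided permutation test, whose smallest possible p is 0.1 with 3 libraries in each group. Total counts of 26.8 to 32.4 M reads per library mean that counting error was small beside the spread between libraries for most genes named. Within a genotype, pairs of libraries differed by 23.3 to 78.1 times the variance that counting alone gives (chi-square per degree of freedom; counting each mate as 1 read inflates this about 2 times), so no library was a copy of another. The first principal component of log2 CPM held 42.1% of the variance and separated the genotypes, and the second held 21.6% and set wild-type replicate 1 apart. The order of the libraries on the first component was the exact reverse of the order of their skeletal muscle list scores, within each genotype too. The first component therefore does not tell genotype from muscle RNA.

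Before the data were examined, 32 gene lists were fixed, covering collagens, collagen processing, bone matrix, bone cells, signalling responses, stress, energy metabolism and the other cell types a flushed tibia can hold. Lists of 13 mitochondrially encoded protein genes and of ribosomal proteins (85 tested) were taken from the annotation, and ribosomal protein kinases, whose symbols begin alike, were left out of the second after its members were seen. Some genes stand in several lists, such as Fn1 in the matrix and TGF-beta response lists and Omd in the matrix and osteoblast lists. The 34 lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with the correlation estimated per list, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. By camera 17 lists were higher and 6 lower, with an estimated correlation 0 passed (smallest adjusted p = 0.232, with 6 lists at an unadjusted p under 0.05), and by fry 8 passed (smallest adjusted p = 0.0298). Genes named in the text follow a rule also fixed before the data were examined: Col1a1, then the 10 largest log2 fold changes in each direction among called genes with a mean of at least 1 CPM, no overlap between genotypes, a symbol and no predicted-model name, then of each list up to 4 members, the 2 with the smallest p in each direction. Col1a2, Col5a2, Sparc, Sox9, Ihh and further fibre-type genes were named after their values were seen. Some genes are not reported here. Genes near Col1a1 were those starting within 10 Mb of it.

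The pipeline was tested on simulated counts with the means and library sizes of these 6 libraries, 18514 genes and 200 changed genes, in this comparison of 3 against 3. EdgeR found 22.4% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 92.4% of those changed 4-fold, and 9.92% of its calls were unchanged genes. DESeq2 1.42.0 found 35.8%, 76.1% and 97%, with 26.1% of its calls unchanged genes, and limma-voom 13.4%, 56.7% and 92.4%, with 9.24%. In simulated data without change camera called 0 lists. Genes were drawn independently of each other there, so this does not test the preset correlation. In the real data the estimated correlation ran from -0.00128 (immediate early genes) to 0.973 (neutrophil markers). It was 0.58 for collagen processing and 0.791 for skeletal muscle.

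Alternatives fixed before the data were examined were another normalization (RLE or library totals), DESeq2 or limma-voom, a fit without robust estimates, other filters and thresholds, a block for the replicate number, each library left out in turn, marker genes of muscle, erythroid cells and neutrophils left out, and scores of these cells as covariates. A further 3 choices, halved counts, scaling on the osteocyte list and other reference genes for the Col1a1 ratio, were added after the data were seen. No sample or column was left out, and figures were drawn with matplotlib 3.10.9.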

Results

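RNA was sequenced from the tibia of female mice 12 weeks old, in 3 samples labelled heterozygous for the type I collagen gene Col1a1 (Col1a1+/-) and 3 wild-type samples. Loss of 1 functional Col1a1 copy is the usual basis of osteogenesis imperfecta type I, a brittle bone disease, and the series presents these mice as a model of it. Marrow was flushed from the bones before they were frozen and ground, and libraries were made from polyadenylated RNA. Each library is a table of read counts for 56748 genes, with a total between 26.8 and 32.4 M reads. The genotypes differed in depth by less than the spread between libraries, at 29.2 ± 2.8 M reads in Col1a1+/- and 30.5 ± 1.66 M in wild type (SD, n = 3 each). The labels do not say whether each sample came from a separate animal, so p-values measure only the spread between these samples. With 3 samples against 3, an exact permutation test cannot give a two-sided p below 0.1.

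Col1a1, which encodes the alpha 1 chain of type I collagen, was not lower in the Col1a1+/- libraries, although its level relative to the partner chain gene was. Col1a1 (ENSMUSG00000001506; chromosome 11, 94827050 to 94843868, GRCm39, plus strand, 6563 bp of exon) took 61150, 52880 and 59600 counts-per-million (CPM) in Col1a1+/- replicates 1, 2 and 3 and 36810, 61350 and 54800 CPM in the wild-type replicates. The means were 57880 ± 4390 and 50990 ± 12700 CPM (SD, n = 3 each), a log2 fold change of 0.18 (SE 0.31, adjusted p = 0.78 by edgeR; exact permutation p = 0.7). The sign of this change turned under 2 alternatives, to -0.26 with libraries scaled on osteocyte genes and to -0.12 with an erythroid and neutrophil covariate. Col1a2, which encodes the alpha 2 chain and was singled out after the values were seen, stood at 71250 ± 2670 CPM in Col1a1+/- against 40040 ± 10900 CPM in wild type. Its log2 fold change was 0.83, with all 3 Col1a1+/- libraries above all 3 wild-type libraries (adjusted p = 0.159; exact permutation p = 0.1, the smallest possible).

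The ratio of Col1a1 to Col1a2 counts, which does not depend on how libraries are scaled, was 0.836, 0.775 and 0.823 in Col1a1+/- and 1.32, 1.25 and 1.27 in wild type. The mean ratio of 0.812 ± 0.032 in Col1a1+/- was 0.634 times that of 1.28 ± 0.0357 in wild type (SD, n = 3 each; exact permutation p = 0.1). Measured against Col5a2, a type V collagen gene, Col1a1 was at 0.6 times the wild-type ratio, and against Sparc, which encodes the matrix protein osteonectin, at 0.634 times. The fibrillar collagen, collagen processing, non-collagen matrix, osteoblast and osteocyte lists together held 88 tested genes besides Col1a1. Of these, 78 had a log2 fold change above that of Col1a1, and the median was 0.64 (quartiles 0.46 and 0.83). The lists of other collagens and of osteoclast markers were not included, and their medians were 0.49 and 0.36. The level of Col1a1 therefore did not check the genotype labels, whereas its ratio to Col1a2 parted all libraries as labelled. That reference gene was singled out after the values were seen, so the ratio is no independent check of the labels.

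**Figure D1:**
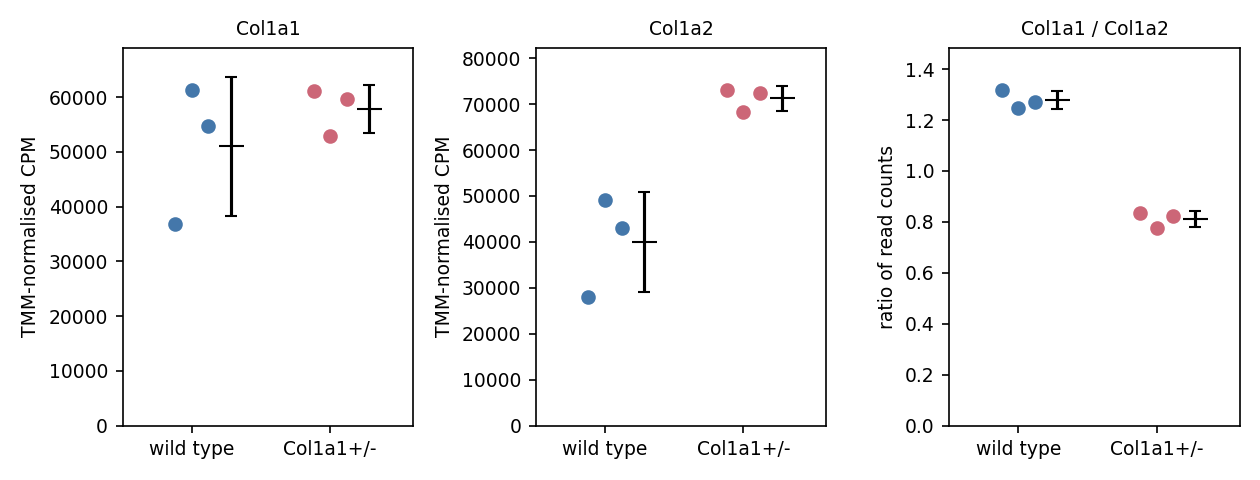
Level of Col1a1 and Col1a2 (TMM-normalised CPM) and the ratio of their read counts in each tibia library, by genotype. Points are libraries, and the bar beside them is the mean with its SD (n = 3 each). Col1a1 overlaps between genotypes, and the ratio lies between 0.775 and 0.836 in Col1a1+/- and between 1.25 and 1.32 in wild type.

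Between the genotypes, 803 of 18514 tested genes passed an adjusted p of 0.05, with 265 higher and 538 lower in Col1a1+/-. The higher genes were mostly modest in size, with a median fold of 1.59 and 45 genes at 2-fold or more, and the lower genes changed more, with a median fold of 2.04 and 274 genes at 2-fold or more. All 803 genes had 3 libraries of 1 genotype on the same side of all 3 of the other, which held for 28.6% of all tested genes, where chance gives 10%. The genotypes also differed in skeletal muscle RNA: a list of 24 muscle genes took 2.83% ± 1.18 of counts in Col1a1+/- and 7.13% ± 1.02 in wild type (SD, n = 3 each; exact permutation p = 0.1). The number of called genes rested on single libraries. It was 8 without wild-type replicate 2, 44 without Col1a1+/- replicate 3 and 1766 without wild-type replicate 1, which stood apart in neutrophil transcripts (0.67% of counts, against 0.112% to 0.186% in the other libraries). Without wild-type replicate 3 or without Col1a1+/- replicate 1, edgeR called 0 genes, with 3239 and 3275 at an unadjusted p under 0.05 (4228 with all libraries). In those same comparisons limma-voom called 0 genes, and DESeq2 called 1136 and 1159. With 1 library left out the median log2 fold change of the 265 higher genes lay between 0.63 and 0.74. That of the 538 lower genes lay between -1.158 and -0.905. These genes were chosen with all 6 libraries, so their medians cannot show how stable the folds are. Single genes moved further, such as the slow troponin gene Tnni1 (-5.705 to -3.673). With libraries scaled on osteocyte genes, an alternative added after the data were seen that lowers the median of all genes to -0.51, 27 genes were higher and 2495 lower, so that 1.07% of calls were higher in place of 33%.

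Genes for collagens and for the enzymes that fold, modify and crosslink them were higher in Col1a1+/-. Of 10 fibrillar collagen genes other than Col1a1, 4 rose and none fell, 8 adjusted over the list alone, with a median log2 fold change of 0.81. Among them were Col5a1 (1.77-fold; 1165 ± 114 against 658 ± 97.1 CPM; adjusted p = 0.036), Col5a2 (log2 fold change 0.93, adjusted p = 0.039) and Col27a1 (1.56-fold, adjusted p = 0.0286). Of 31 genes for collagen folding, modification and processing, 15 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.64. Creb3l1, a transcription factor for procollagen genes and their secretory machinery, rose from 145 ± 26.1 to 323 ± 36.3 CPM (log2 fold change 1.16, SE 0.16, adjusted p = 0.0212). Loxl4, which encodes a lysyl oxidase that crosslinks collagen, rose 1.97-fold (log2 fold change 0.98, SE 0.12, adjusted p = 0.0192). The member that fell was Tmem38b, which encodes an endoplasmic reticulum cation channel (log2 fold change -0.75, SE 0.11, adjusted p = 0.0216). Of 18 other collagen genes 1 rose, Col13a1 (log2 fold change 0.62, adjusted p = 0.0457; 5 genes over the list alone), and Col6a2 stood at 0.83 (adjusted p = 0.055). The non-collagen bone matrix list, with 21 genes tested, held 4 that rose (10 adjusted over the list alone) and a median of 0.59. Fibronectin (Fn1) rose from 1128 ± 87.7 to 2421 ± 216 CPM (log2 fold change 1.10, SE 0.17, adjusted p = 0.0232), and osteomodulin (Omd) rose 1.79-fold (log2 fold change 0.84, SE 0.10, adjusted p = 0.0192).

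By camera these lists were higher than other genes, with adjusted p = 5.21e-09 for fibrillar collagens, 7.01e-20 for collagen processing, 3.84e-05 for other collagens and 9.35e-12 for non-collagen matrix. With an estimated correlation the adjusted p was 0.232 for all of these except other collagens, for which it was 0.288. Without wild-type replicate 2, wild-type replicate 3 or Col1a1+/- replicate 1 none of the fibrillar collagen, collagen processing or matrix genes kept its call by edgeR. Without Col1a1+/- replicate 3 the numbers that were higher were 0, 1 and 2, and without Col1a1+/- replicate 2 the fibrillar collagens had 1. The other collagens had 1 called gene without wild-type replicate 1 and 0 with any other library left out. When libraries were scaled on osteocyte genes, 0 fibrillar collagens, 0 processing genes and 1 matrix gene were called higher and 1 processing gene lower. The medians of these lists were then 0.36, 0.18 and 0.13, and that of the other collagens, with 0 called, turned to -0.02. With library totals in place of TMM, 8 fibrillar collagens, 21 processing genes, 9 matrix genes and 5 other collagens were called higher. The erythroid and neutrophil covariate left 1, 3, 2 and 0, and the muscle covariate 0 in each list, where edgeR called 0 genes overall (1078 at an unadjusted p under 0.05). The list medians with the muscle covariate were 0.94, 0.52, 1.05 and 0.48 in the same order, so the calls were lost without a like fall of the medians. The muscle list took 2.83% of counts in Col1a1+/- and 7.13% in wild type, as above.

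Markers of osteoblasts, the cells that lay down bone matrix, rose in Col1a1+/-. Of 20 osteoblast markers 12 rose and none fell (16 adjusted over the list alone), with a median log2 fold change of 0.74, and the list took 1.6% ± 0.11 of counts against 0.874% ± 0.1 in wild type (SD, n = 3 each; exact permutation p = 0.1). Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that restrains osteoclast formation, rose from 12.5 ± 1.67 to 33.8 ± 9.75 CPM (log2 fold change 1.43, SE 0.22, adjusted p = 0.0239). Of 13 markers of osteocytes, the cells embedded in bone, 0 passed the threshold, with 0 over the list alone and a median of 0.52. Their smallest p belonged to Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL (log2 fold change 0.68, adjusted p = 0.0628), and Gja1 (0.49, adjusted p = 0.0865). Of 16 markers of osteoclasts, which resorb bone, 0 passed the threshold, with 0 over the list alone and a median of 0.36; Src stood at 0.38 (adjusted p = 0.0993) and Ocstamp at 0.72 (adjusted p = 0.111). DESeq2 called 3 genes in each of these last 2 lists. Among 18 matrix metalloproteinases and inhibitors 3 rose, including Mmp23 (log2 fold change 0.71, adjusted p = 0.0321) and Mmp16 (0.68, adjusted p = 0.0336), whereas the inhibitor Timp4 stood at -1.44 (adjusted p = 0.0576).

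By camera all of these lists were higher, with adjusted p = 9.85e-19 for osteoblast, 1.23e-03 for osteocyte, 2.48e-04 for osteoclast and 4.36e-03 for metalloproteinase genes. The adjusted p was 0.232, 0.486, 0.462 and 0.354 in the same order with an estimated correlation. Without wild-type replicate 1 the osteocyte list no longer passed (adjusted p = 0.063). The called osteoblast genes numbered 0 without wild-type replicate 2, wild-type replicate 3 or Col1a1+/- replicate 1, 2 without Col1a1+/- replicate 3 and 7 without Col1a1+/- replicate 2. The metalloproteinase list had 0 called genes when wild-type replicate 2 or 3 or Col1a1+/- replicate 1 or 3 was left out. Scaling on osteocyte genes left 1 osteoblast gene called, kept the osteoblast median above 0 at 0.28 and turned the osteoclast and metalloproteinase medians to -0.12 and -0.18, with 0 and 2 of these genes called lower and 0 higher. Of osteoblast genes edgeR called 15 as higher with library totals, 3 with the erythroid and neutrophil covariate and 0 with the muscle covariate, with list medians of 0.84, 0.56 and 0.80. All 3 Col1a1+/- libraries had a higher osteoblast score and a lower muscle score than all 3 wild-type libraries. Within wild type the library with the lowest muscle score, replicate 1, also had the lowest osteoblast score. Within Col1a1+/- the osteoblast scores hardly differed, at 8.061 to 8.168.

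**Figure D2:**
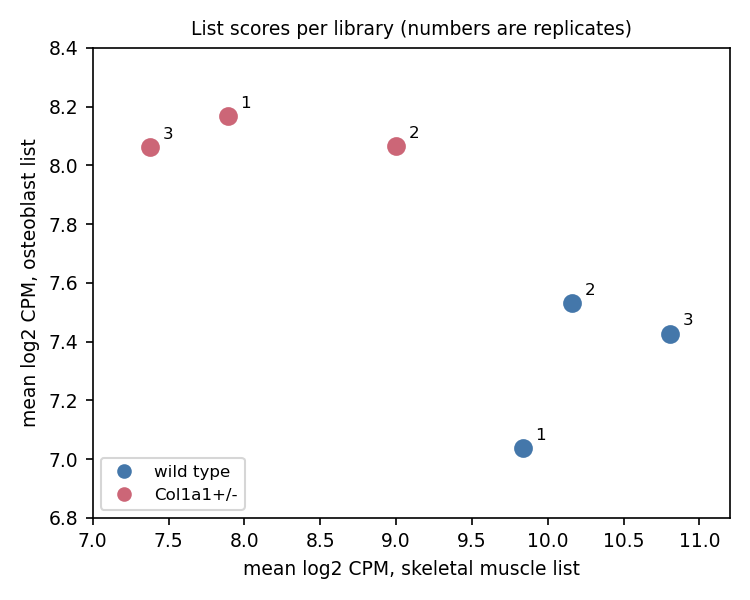
Mean log2 CPM of 24 skeletal muscle markers (horizontal axis) against that of 20 osteoblast markers (vertical axis) in each tibia library, with points coloured by genotype and numbered by replicate. The osteoblast score was 8.1 ± 0.0604 in Col1a1+/- and 7.33 ± 0.26 in wild type, and the muscle score 8.09 ± 0.831 and 10.3 ± 0.495 (SD, n = 3 each).

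The title of the series names a treatment against TGF-beta, whereas the labels of these 6 samples name none, so the TGF-beta genes were compared between genotypes alone. Of 20 TGF-beta response genes 4 rose and none fell (8 adjusted over the list alone), with a median log2 fold change of 0.30. They included Ccn2, a matrix-associated growth factor target (log2 fold change 0.79, SE 0.13, adjusted p = 0.0239), and Fn1. Among 20 TGF-beta ligands, receptors and binding proteins 1 rose (4 over the list alone), the matrix proteoglycan biglycan (Bgn), from 1297 ± 222 to 2346 ± 203 CPM (log2 fold change 0.85, adjusted p = 0.0424). The latent TGF-beta binding protein gene Ltbp1 stood at 0.44 (adjusted p = 0.0581) and the ligand gene Tgfb2 at -0.40 (adjusted p = 0.124). All 13 BMP response genes had a fold change above 0, with a median of 0.52, and 3 rose (9 over the list alone). These included Hey1 (log2 fold change 0.64, adjusted p = 0.0336) and Msx2, which was at 0.683 CPM in Col1a1+/- and 0.0655 CPM in wild type, too low there for a fold. Of 16 Wnt response genes 4 rose (5 over the list alone), with a median of 0.41, among them Lgr6 (2.75-fold; log2 fold change 1.46, SE 0.18, adjusted p = 0.0192) and Tcf7 (1.67-fold, adjusted p = 0.024).

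By camera the lists gave adjusted p = 6.47e-05 for TGF-beta response, 0.0299 for TGF-beta ligands and receptors, 6.68e-08 for BMP response and 5.94e-08 for Wnt response. With an estimated correlation the adjusted p was 0.232, 0.371, 0.232 and 0.232. The ligand and receptor list did not pass without wild-type replicate 1 (adjusted p = 0.0611) or Col1a1+/- replicate 2 (0.0726). With wild-type replicate 2, wild-type replicate 3 or Col1a1+/- replicate 1 left out, edgeR called none of these genes. Without Col1a1+/- replicate 3 the TGF-beta and Wnt response lists had 1 called gene each and the other lists 0. Leaving out wild-type replicate 1 gave 7, 3 and 6 called genes in the TGF-beta response, ligand and BMP lists, and leaving out Col1a1+/- replicate 2 gave 2, 0 and 1. Relative to osteocyte genes the medians of the TGF-beta response, TGF-beta ligand and Wnt lists turned to -0.20, -0.32 and -0.07, and that of the BMP list was 0.03; 1 BMP and 1 Wnt gene were then called higher and 1 TGF-beta ligand or receptor gene lower. Muscle RNA was lower in the same libraries, as given above.

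Genes for protein folding in the endoplasmic reticulum were slightly higher as a list, in libraries that also held less muscle RNA. Of 24 unfolded protein response genes 2 rose and 1 fell (7 and 1 over the list alone), with a median of 0.18 (camera adjusted p = 1e-03, and adjusted p = 0.354 with an estimated correlation). Manf (1.55-fold, adjusted p = 0.0238) and the disulfide isomerase gene Pdia4 (1.59-fold, adjusted p = 0.0458) rose. Chac1, a glutathione-degrading enzyme induced by ATF4, fell from 32.2 ± 12.4 to 11.4 ± 2.09 CPM (log2 fold change -1.50, SE 0.30, adjusted p = 0.0436). Among 13 heat shock genes Hsph1 fell (log2 fold change -0.69, adjusted p = 0.0279; 1 higher and 4 lower over the list alone), with a median of -0.24 (camera adjusted p = 0.188, and 0.0189 without wild-type replicate 1). Of 17 immediate early genes Ccn1 rose (log2 fold change 0.66, adjusted p = 0.0399; 4 over the list alone), with a median of 0.16 (camera adjusted p = 0.0329, and adjusted p = 0.232 with an estimated correlation). None of these genes was called without wild-type replicate 2, wild-type replicate 3, Col1a1+/- replicate 1 or Col1a1+/- replicate 3 by edgeR, and 6 unfolded protein response genes were higher without wild-type replicate 1. The unfolded protein median was 0.32 without wild-type replicate 1, against 0.18 with it. On the osteocyte scale the medians of the unfolded protein and immediate early lists were -0.33 and -0.35, with 0 genes higher and 1 lower in each, and the heat shock median was -0.70, with 4 lower. With the muscle covariate the unfolded protein median was 0.02 and edgeR called 0 of these genes. Without wild-type replicate 1 the heat shock list had 1 higher and 3 lower. The immediate early list also lost its camera call without wild-type replicate 1 (adjusted p = 0.0506), wild-type replicate 2 (0.0841) or Col1a1+/- replicate 2 (0.107).

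Cartilage genes had the highest list median. All 16 chondrocyte markers had a fold change above 0, with a median log2 fold change of 1.203, and 6 rose (10 over the list alone). Col10a1, the collagen of hypertrophic cartilage, rose from 60 ± 25.2 to 265 ± 46.2 CPM (log2 fold change 2.14, SE 0.30, adjusted p = 0.024), aggrecan (Acan) from 75.8 ± 15.6 to 212 ± 48.6 CPM (1.48, SE 0.21, adjusted p = 0.0218), and the chondrocyte transcription factor Sox9 (1.05, adjusted p = 0.0246) and the signalling ligand Ihh (1.44, adjusted p = 0.0383) rose with them. Clec3a, a cartilage-derived lectin, was the largest change among called higher genes with a mean of at least 1 CPM that met the fixed rule (4.53-fold; 128 ± 63 against 28.3 ± 6.47 CPM; adjusted p = 0.0481). The camera test gave adjusted p = 1.42e-14, and adjusted p = 0.241 with an estimated correlation; the list score overlapped between genotypes (exact permutation p = 0.2). In this list edgeR called 1 gene without wild-type replicate 2, 0 without wild-type replicate 3 or Col1a1+/- replicate 1, 5 without wild-type replicate 1, and 4 without Col1a1+/- replicate 2, without Col1a1+/- replicate 3 or on the osteocyte scale. It called 9 with library totals, 3 with the erythroid and neutrophil covariate and 0 with the muscle covariate, where the median was 1.94. The muscle list took less of the counts in the same Col1a1+/- libraries. The other 8 of the 10 largest increases were Moxd1, Itih2, Serpina1e, Stk32b, Meltf, Ppp1r1b, Tecrl and Scn1a, at 3.11-fold to 4.47-fold, with mean levels in Col1a1+/- from 1.97 CPM (Tecrl) to 73.2 CPM (Meltf). In wild type their means ran from 0.623 CPM (Tecrl) to 20.5 CPM (Meltf), so the folds of the lowest are uncertain. Serpina1e belongs to a family of near-identical genes, so its count is uncertain.

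Skeletal muscle genes fell in Col1a1+/-. All 24 muscle markers had a fold change below 0, with a median log2 fold change of -1.54, and 10 fell (24 adjusted over the list alone). The ryanodine receptor gene Ryr1 stood at 533 ± 183 CPM against 1557 ± 359 CPM in wild type (log2 fold change -1.55, SE 0.27, adjusted p = 0.0279), and nebulin (Neb) at 660 ± 249 against 1990 ± 486 CPM (-1.59, SE 0.29, adjusted p = 0.03). Among called genes with a mean of at least 1 CPM that met the fixed rule, the largest decreases were in genes of slow-twitch fibres: Tnni1, slow troponin I, at 2.13 ± 1.97 against 52.5 ± 44 CPM (log2 fold change -4.63, SE 0.89, adjusted p = 0.0471), and Myl2, the slow regulatory light chain, at 6.07 ± 3.97 against 118 ± 85.5 CPM (-4.28, SE 0.73, adjusted p = 0.0396). The next 8 by that rule were Slco4c1, Ildr1, Iqsec3, Pm20d2, Klhl34, Shisa3, Barx2 and Inpp5j, each 4.29-fold to 4.75-fold lower. Their mean levels ran from 0.404 CPM (Iqsec3) to 2.4 CPM (Klhl34) in Col1a1+/- and from 1.86 CPM (Iqsec3) to 11 CPM (Klhl34) in wild type. The folds of the lowest are therefore uncertain. Of 32 genes of oxidative phosphorylation, the mitochondrial pathway of ATP synthesis, all had a fold change below 0, with a median of -0.83 and Uqcrc2 (-0.87, adjusted p = 0.0523) and Sdha (-0.79, adjusted p = 0.0544) the closest to the threshold. In that list edgeR called 0 genes over all genes and 22 over the list alone, and DESeq2 called 27. The 13 mitochondrially encoded protein genes had a median of -0.95 and 0 called (0 over the list alone; 7 by DESeq2). Mitochondrial transcripts took 5.04% ± 1.21 of counts in Col1a1+/- and 8.11% ± 1.28 in wild type (SD, n = 3 each).

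The camera adjusted p was 1.56e-23 for muscle, 5.86e-14 for oxidative phosphorylation and 1.79e-05 for mitochondrially encoded genes, and the adjusted p was 0.232, 0.372 and 0.459 with an estimated correlation. The called muscle genes numbered 0 without wild-type replicate 2, wild-type replicate 3, Col1a1+/- replicate 1 or Col1a1+/- replicate 3, and 20 without Col1a1+/- replicate 2. Without wild-type replicate 1 edgeR called 30 oxidative phosphorylation and 6 mitochondrially encoded genes as lower. With the muscle score as a covariate the medians of the oxidative phosphorylation and mitochondrially encoded lists turned to 0.23 and 0.17. With osteocyte scaling edgeR called 20 muscle, 32 oxidative phosphorylation and 12 mitochondrially encoded genes as lower, and with library totals 19, 15 and 0.

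Among the blood and marrow cell lists, few genes passed the threshold with TMM scaling. Megakaryocyte and platelet markers were lower, with 2 of 11 falling (7 over the list alone) and a median log2 fold change of -0.54 (camera adjusted p = 1.34e-05, and adjusted p = 0.354 with an estimated correlation). These 2 were Vwf, encoding von Willebrand factor (-0.71, SE 0.11, adjusted p = 0.0238), and the platelet receptor gene Gp1ba (-0.90, SE 0.20, adjusted p = 0.043). The 14 B cell markers had a median of -0.37 and 0 called over all genes (5 over the list alone; 1 by DESeq2), with camera adjusted p = 3.28e-03 and adjusted p = 0.232 with an estimated correlation; Vpreb1 stood at -0.84 (adjusted p = 0.0719). All 18 neutrophil markers had a fold change below 0, with a median of -1.27 (camera adjusted p = 8.11e-05, and adjusted p = 0.523 with an estimated correlation) that was -0.34 without wild-type replicate 1. In that list 0 genes passed over all genes, over the list alone and by DESeq2; Elane stood at -1.45 (adjusted p = 0.168) and Fcnb at -1.65 (adjusted p = 0.14). Marrow adipocyte genes went both ways, with 6 of 11 above 0 and 5 below, a median of 0.03 and a mean of -0.25 (camera adjusted p = 0.0791). Of the 11, 2 fell (3 over the list alone): the lipid droplet coat gene Plin4 (-1.15, SE 0.18, adjusted p = 0.0238) and lipoprotein lipase (Lpl, -0.97, SE 0.21, adjusted p = 0.0449). The adipocyte list passed as lower by camera without wild-type replicate 1 (median -0.20) or Col1a1+/- replicate 1 (median -0.23). Of 15 erythroid markers 1 fell, the membrane skeleton gene Sptb (-0.84, adjusted p = 0.0257), with a list median of -0.02 (camera adjusted p = 0.789). In this list 7 genes had a fold change above 0 and 8 below, and the median lay between -0.15 and 0.21 without 1 library. Vwf, Gp1ba, Plin4, Lpl and Sptb were each uncalled by edgeR without wild-type replicate 2, wild-type replicate 3, Col1a1+/- replicate 1 or Col1a1+/- replicate 3, and 1 of the 2 megakaryocyte genes without Col1a1+/- replicate 2. With osteocyte scaling the adipocyte median turned to -0.44, and edgeR called 14 neutrophil, 7 B cell, 9 megakaryocyte, 3 adipocyte and 1 erythroid gene as lower. The muscle share was lower in the same Col1a1+/- libraries, and with the muscle covariate edgeR called 0 genes. The megakaryocyte and B cell medians were then -0.02 and -0.04. Those of the erythroid, adipocyte and neutrophil lists were 0.06, -0.18 and -2.51. Whether the megakaryocyte and B cell genes, Plin4, Lpl and Sptb fell in marrow cells or with the muscle share was not tested.

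**Figure D3:**
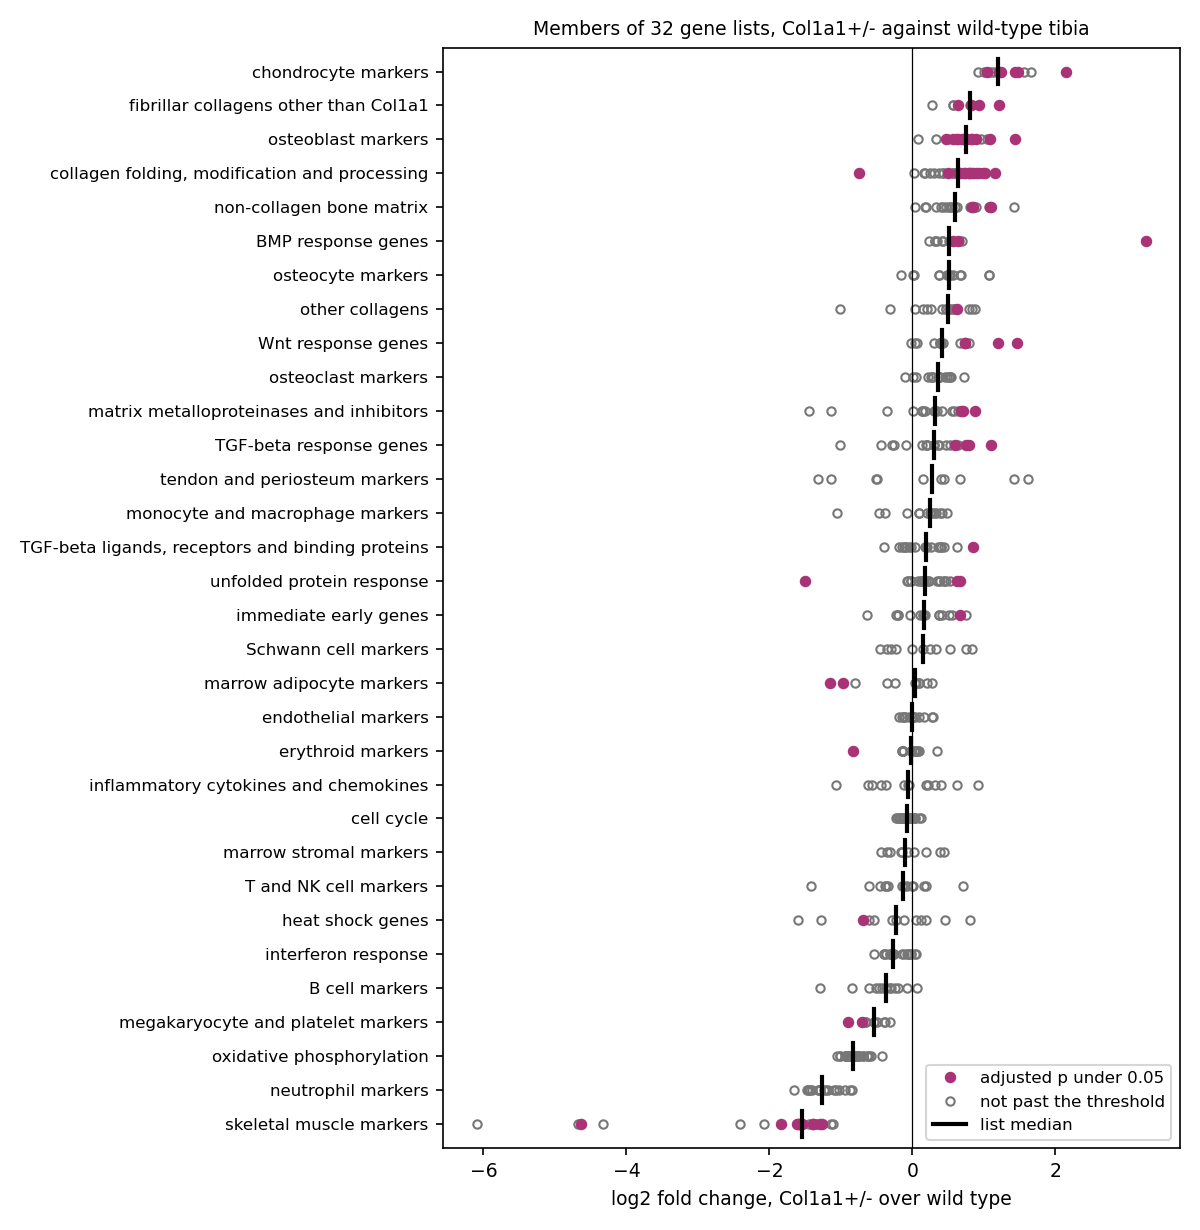
Log2 fold change of each tested member of 32 gene lists, Col1a1+/- over wild type, with 1 list per row ordered by its median. Filled points passed an adjusted p of 0.05 by edgeR over all genes, open points did not, and the black bar is the list median. Medians run from -1.54 for skeletal muscle to 1.203 for chondrocyte markers; scaling on osteocyte genes puts the median of all genes at -0.51 and turns 12 of these list medians from above 0 to below it.

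A region around Col1a1 was compared with the rest of the genome, since a modified allele can carry flanking DNA of another strain. Within 10 Mb of Col1a1, 16 of 333 tested genes were called (4.8%), against 787 of 18180 elsewhere (4.33%; odds ratio 1.12, 95% interval 0.627 to 1.85, Fisher's exact test p = 0.682, two-sided). At an unadjusted p under 0.05 the odds ratio was 0.982 (Fisher's exact test p = 0.947).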

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

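Settings with halved counts, scaling on the osteocyte list, and other reference genes for the Col1a1 ratio were chosen after the data were seen. The 803 called genes (265 higher, 538 lower) numbered 1327 (588 higher) with library totals alone, 2078 (695 and 1383) with DESeq2, which in simulation also made the most false calls, 1472 (577 and 895) without a filter, 319 (45 and 274) with an absolute log2 fold change of at least 1, and 2522 (27 and 2495) with scaling on osteocyte genes. The higher share of calls was 33% as reported, 44.3% with library totals, 1.07% with osteocyte scaling and 12.6% with the erythroid and neutrophil score as a covariate, where 97 genes were higher. With the muscle score as a covariate edgeR called 0 genes, 0 higher and 0 lower, with 1078 at an unadjusted p under 0.05, and limma-voom 0. At an adjusted p under 0.01 edgeR called 0, 0 higher and 0 lower, limma-voom 0 and DESeq2 1229, with 4228 at an unadjusted p under 0.05 by edgeR. Leaving out 1 library gave 0 to 1766 called genes, 0 to 594 higher and 0 to 1172 lower. Other settings (RLE, limma-voom, no robust estimates, a CPM filter, marker genes left out, halved counts) gave 793 to 957 called genes. For the numbers that changed with a setting, the cause was not tested. Of the 803 genes, 800 were called with RLE, 799 with DESeq2 and 554 with osteocyte scaling. Pairs of libraries of a genotype differed by 23.3 to 78.1 times the variance of counting single reads. Counting mates apart inflates this about 2 times. It is a mean over genes in which those with many reads weigh most. For genes with few reads, such as Iqsec3 (10 to 81 per library), it does not show whether depth or spread limited calls.

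With the replicate number as a block 126 genes were called, 37 higher and 89 lower. Same-numbered libraries correlated at 0.107, 0.041 and -0.122 in their deviations from the genotype means, and not every library correlated best with its own number, so the numbers are not taken to pair the samples. The log2 fold change of Col1a1 was 0.21 with the block.

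The log2 fold change of Col1a1 ranged from 0.026 to 0.337 without 1 library and turned to -0.117 with the erythroid and neutrophil covariate and -0.26 with osteocyte scaling, none with an adjusted p under 0.05; the cause was not tested. The log2 ratio of Col1a1 to Col1a2 between genotypes, -0.658, was -0.68 to -0.625 without 1 library and -0.738 with Col5a2 as the reference. The odds ratio near Col1a1 was 0.982 at an unadjusted p. The 23 lists called by camera became 0 with an estimated correlation and 8 by fry, and 21 to 25 without 1 library. Lists whose camera test turned direction had medians, with the muscle covariate, of osteoclast -0.074, oxidative phosphorylation 0.232, skeletal muscle -0.046 (still below 0; these genes make up the covariate), macrophage -0.17 and mitochondrially encoded 0.165; with the erythroid and neutrophil covariate, cell cycle 0.334, neutrophil 0.138, T and NK cell 0.385 and ribosomal -0.092; and without wild-type replicate 1, cell cycle 0.215 (-0.209 to 0.215 without 1 library).

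Among named genes, 55 of 86 passed the threshold and 0 of these turned sign. Of the others, log2 fold changes turned with osteocyte scaling for Src (-0.112), Ltbp1 (-0.07), Cd68 (-0.005), Rpl3 (-0.121), Foxc1 (-0.091) and Emcn (-0.212), with the muscle covariate for Ocstamp (-0.137), Uqcrc2 (0.02), Sdha (0.008) and Emcn (-0.034), and with the erythroid and neutrophil covariate for Pcna (0.05).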

Other observations

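Tests of the Col1a1 ratio and of slow against fast fibres were chosen after their results had been seen. So were those of the osteoblast against the B cell, megakaryocyte, osteoclast and osteocyte scores. Tests of muscle slopes, of wild-type replicate 1, of the muscle covariate and of other splits were set before their own results were seen. The patterns they address came from these data.

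With TMM scaling several cell types and programmes of the tibia had medians near 0. With osteocyte scaling, which lowers the median of all genes to -0.51, the cell cycle, endothelial, stromal, interferon and T and NK cell medians were -0.64, -0.48, -0.60, -0.72 and -0.67. The 25 cell cycle genes had a median log2 fold change of -0.07 and 0 called by edgeR, DESeq2 or over the list alone (camera adjusted p = 0.82), with Pcna at -0.13 (adjusted p = 0.512). Endothelial markers, 14 genes, had a median of 0.00 (camera adjusted p = 0.789), with Emcn at 0.29 and Ptprb at -0.18, and marrow stromal markers a median of -0.11 (camera adjusted p = 0.933), with Cxcl12 at -0.36 (adjusted p = 0.194) and Foxc1 at 0.39 (adjusted p = 0.0624). With library totals in place of TMM the endothelial median was 0.09 and that of inflammatory cytokines turned to 0.03. Interferon response (median -0.27, camera adjusted p = 0.236), inflammatory cytokines (-0.06, adjusted p = 0.674), T and NK cells (-0.13, adjusted p = 0.674) and Schwann cells (0.15, adjusted p = 0.183, with S100b at 0.52, adjusted p = 0.0586) did not pass. Without wild-type replicate 3 the cell cycle and interferon lists did pass as lower, with medians of -0.21 and -0.44, whereas without wild-type replicate 1 the cell cycle list passed as higher, at 0.22. Leaving out 1 library moved the cytokine median between -0.19 (wild-type replicate 3) and 0.23 (wild-type replicate 2) and the T and NK cell median between -0.62 (Col1a1+/- replicate 1) and 0.06 (Col1a1+/- replicate 2), none past the threshold. The stromal median lay between -0.22 and 0.10 in these settings, at 0.10 without wild-type replicate 1. Without Col1a1+/- replicate 3 the Schwann list passed as higher, at 0.21. Ribosomal proteins (0.12, adjusted p = 2.3e-03; 0.763 with an estimated correlation; Rpl3 at 0.38) and macrophage markers (0.24, adjusted p = 0.0424; 0.523 with an estimated correlation; Cd68 at 0.49) passed as slightly higher, and with osteocyte scaling these medians turned to -0.35 and -0.25. Of these, the ribosomal list lost its call without wild-type replicate 1 (median 0.03), and the macrophage list lost it without wild-type replicate 2, wild-type replicate 3 or Col1a1+/- replicate 1 (medians 0.32, 0.19 and 0.18). Tendon and periosteum markers split (median 0.27, camera adjusted p = 0.347), with the cartilage intermediate layer gene Cilp at 1.62 (adjusted p = 0.063) and Chad at 1.42 (adjusted p = 0.0602), and 2 members higher and 2 lower over the list alone; without Col1a1+/- replicate 3 the list passed as higher (median 0.29). With osteocyte scaling the tendon and Schwann medians turned to -0.21 and -0.34. DESeq2 called 2 stromal, 2 Schwann and 1 macrophage gene as higher, 2 tendon genes as higher and 2 as lower, and 1 ribosomal gene each way, where edgeR called 0 in each of these lists.

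The lower muscle genes were weighed first. If less muscle came with the Col1a1+/- bones, other lower genes should follow the muscle score among libraries of one genotype too. The 528 called lower genes outside the muscle list were followed. Their slope on the muscle score within genotypes was a median 0.678 of that between genotypes (quartiles 0.451 and 0.844). Less muscle RNA behind most of the decreases would give this, and so would any other source of the same order of libraries. The first principal component held that order reversed, within genotypes too, and slopes of other gene sets were not computed. Less of one and the same muscle tissue is argued against: the slow minus fast fibre score was lower by 3.74 in Col1a1+/-, apart in all libraries (log2; larger SD 1.01), with Myh7 at -6.10 and Tnnt1 at -4.32 (adjusted p = 0.0576 and 0.0533) against Myh4 at -1.13 and Actn3 at -1.27. A candidate explanation is that more muscle, with a larger part of slow fibres, remained on the wild-type bones, since the fast-fibre score differed too (-1.441, no overlap); whether dissection or genotype set this stays open, since the labels do not describe how muscle was removed.

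Dilution by muscle alone would raise other cell types alike. For the higher osteoblast and collagen genes it is argued against only relative to B cells and megakaryocytes. The osteoblast minus B cell score was higher by 1.18 in Col1a1+/- (larger SD 0.322, no overlap between libraries). The osteoblast minus megakaryocyte score was higher by 1.343 (larger SD 0.337, no overlap). The B cell and megakaryocyte scores themselves differed by -0.41 and -0.58, which is part of these differences. With the muscle covariate the B cell and megakaryocyte medians were -0.04 and -0.02, so neither list is shown to be a neutral reference. Flushing that removed marrow to differing extents is not excluded by these scores. Other bone cells did not part as clearly: the osteoblast minus osteoclast score, the contrast tried first, differed by 0.448, without overlap but within 2 times its larger SD of 0.25, and the osteoblast minus osteocyte score by 0.244, with overlap between genotypes (larger SD 0.281, exact permutation p = 0.4). Relative to other bone cells, dilution by muscle alone therefore stays undecided. Wild-type replicate 1 alone is also argued against, since the osteoblast median was 0.61 without it and 0.74 with it. With the muscle score as a covariate the median log2 fold change of the 265 higher genes went from 0.667 to 0.638, and their median SE from 0.132 to 0.271, so their calls ended with the wider error, whereas the 538 lower genes went from -1.03 to -0.31 with an SE from 0.184 to 0.265, mainly a smaller fold; the score separates the genotypes, so that genotype and muscle share cannot be told apart gene by gene. More bone or cartilage tissue in the Col1a1+/- samples stays open too, as all 16 chondrocyte markers had fold changes above 0 (median 1.203, 6 called, with a list score that overlapped between genotypes). A raised osteoblast programme as an effect of the genotype also stays open, as a hypothesis that was not tested.

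The Col1a1 level was weighed as the third pattern. No library had a Col1a1 to Col1a2 ratio among those of the other genotype. The smallest gap between the log2 ratios of the genotypes was 0.579. Col1a2 was singled out after its values were seen, and 28.6% of all tested genes parted the genotypes without overlap. The ratio is therefore no independent test for a mislabelled library. Muscle share or library scaling as the sole cause is argued against, as the mean log2 ratio differed by -0.658 within libraries. The ratio of 0.634 also lies above the 0.5 that an exactly halved Col1a1 would give, with Col1a2 unchanged or raised alike. Against Col5a2 and Sparc the ratios were 0.6 and 0.634. These values argue against 1 allele without counted RNA together with an equal rise of these genes. An unequal rise is not excluded. A hypothesis is that the altered allele still gave some counted RNA while the collagen programme was higher. That would leave Col1a1 itself near the wild-type level. It was not tested, since the counts do not separate alleles.

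Among the 10 splits of the 6 libraries into 3 and 3, the real one called 803 genes and the highest of the others 0 (edgeR), so 1 split gave as many, and 10 splits are too few for a share under 0.05.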
